A study of Mus musculus with 15 samples.

How the data were processed

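Total RNA from frozen distal jejunum was extracted with TRIzol and made into libraries with the NEBNext Ultra II RNA kit, per the labels' protocols. Whether counting used strand is not stated, so a gene and an overlapping or antisense partner were not told apart. Per the submitters' processing notes, FastQC, STAR 2.6.0c, the mm10 build and DESeq2 were used. The read counter and the annotation are not given in the sources used here.

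The main deposited table held 26844 genes in 15 libraries as a signal, DESeq2-normalised counts, per the file headers and the table's own title. In each library 100% of the values were whole multiples of its smallest value above 0, which is what 1 read is worth after division by the library's size factor, so whole reads were recovered. Their totals, 13855034 to 19307079 per library, give the depth. There were also 2 deposited tables of the authors' own DESeq2 comparisons of KO with WT, one per diet, which hold rows with an adjusted p under 0.05. In these the authors gave a mean signal over all libraries, a log2 fold change with its standard error, a p-value with its adjusted value, a Wald score and a fold change (ratio), per the file headers. They were used only where the text names the authors' deposited table. DESeq2 run without a filter on the recovered reads called 424 and 72 genes, the numbers of rows in those tables. Identifiers were matched to GENCODE M21 on GRCm38, the same assembly as mm10, and 26825 of 26844 matched (99.93%).

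Samples were grouped by genotype and diet from the labels. The labels number the replicates but do not say that a number marks a shared cage, litter or day. Each library was taken as 1 mouse. Where the labels do not say so, p-values measure the spread between these samples. The main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), fitted to all 15 libraries so that the 4 groups share 1 estimate of the spread. Genes with a value of at least 10 in at least 3 libraries were tested (14299). P-values were adjusted by Benjamini-Hochberg and genes under 0.05 were called. Called means by limma unless another tool is named. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The files held normalised values, which is why the log-scale test was the main one, and count tests on the recovered reads were alternatives (edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0 and limma-voom, in R 4.3.3).

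There were 36 gene lists, fixed before the data were examined, with 392 genes, of which 389 were in the table. The 34 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks only whether a list's genes move one way. A list's score in a library was the mean log2 level of its tested genes, and scores were compared by two-sided exact permutation tests, adjusted over 20 tests. Genes were named by a rule fixed before the data were examined. It takes Gramd1a, Gramd1b, Gramd1c and Npc1l1, the 8 highest and 8 lowest fold changes among called genes with a group mean of at least 50 (unnamed gene models left out where others were available), up to 6 genes of each list with the smallest p, the 6 smallest p of the interaction, and called genes within 2 Mb of the targeted genes. The genes in the counts of shared calls and the clock genes outside that rule were chosen after their values were seen. Some genes that the rule names are not reported here.

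Tests were tried on simulated data first, with 200 genes changed among about as many genes as in the real table. For KO against WT on the control diet (14082 genes), limma recovered 26.9% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 95.5% of those changed 4-fold, with 9 false calls. For ezetimibe in KO (14084 genes) the shares were 25.4%, 71.6% and 93.9%, with 7 false calls. The simulated genes were drawn independently of each other, without the structure shared by real libraries. The shares and false calls therefore need not hold for the real data. Alternatives were other pseudocounts (0.5 and 5), no filter and a stricter filter (mean of at least 50), TMM and quantile scaling, the libraries of the compared groups alone, robust variance moderation, the replicate number as a block, the 3 count tests, and each library left out in turn. Alternatives chosen after seeing the data were a proliferation score or a clock score as a covariate, DESeq2 without a filter, and leaving out the 2 libraries at the ends of the first principal component. For comparisons that share controls, fold changes of simulated groups without effects were drawn 1000 times. Figures were drawn with matplotlib 3.10.9.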

Results

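RNA was sequenced from the distal jejunum, the last part of the middle small intestine, of male C57BL/6 mice aged 13 to 15 weeks. Wild-type (WT) mice were compared with mice that lack Aster-B and Aster-C in the whole body (KO). Aster proteins, encoded by the Gramd1 genes, bind sterols and carry cholesterol from the plasma membrane to the endoplasmic reticulum without vesicles. All mice ate a diet with 0.08% cholesterol, with or without 0.01% ezetimibe, a drug that blocks the intestinal cholesterol importer NPC1L1. The 15 libraries comprised 4 of WT and 3 of KO on the control diet, and 4 of WT and 4 of KO on ezetimibe. Whole reads recovered from the normalised counts summed to between 13855034 and 19307079 per library. Log2 levels of 2 libraries of the same group correlated across genes with r between 0.966 and 0.987, and no pair agreed within sampling noise. The first principal component held 27.6% of the variance, with WT control replicate 4 at one end and KO ezetimibe replicate 3 at the other. Clock genes differed widely between libraries of the same group, with Dbp, a clock output gene, between 49.5 and 867 normalised counts in WT control and between 41.3 and 911.3 in WT ezetimibe.

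The targeted genes were examined first. Gramd1c, which encodes Aster-C (ENSMUSG00000036292, mm10 chromosome 16, 43980350 to 44063345, minus strand), had 1383 ± 331 normalised counts (SD, n = 4) in WT and 143 ± 44.4 (SD, n = 3) in KO on the control diet. Its log2 fold change in KO was −3.28 ± 0.247 (SE, limma adjusted p = 9.32e-06) on the control diet and −3.34 ± 0.229 (SE, limma adjusted p = 2.31e-06) on ezetimibe. Gramd1b, which encodes Aster-B (ENSMUSG00000040111, mm10 chromosome 9, 40293233 to 40531383, minus strand), fell from 3178 ± 868 (SD, n = 4) to 1146 ± 159.9 (SD, n = 3) on the control diet. That was a log2 fold change of −1.44 ± 0.175 (SE, limma adjusted p = 0.0022). On ezetimibe Gramd1b had 3241 ± 385 (SD, n = 4) in WT and 1837 ± 167 (SD, n = 4) in KO, a log2 fold change of −0.82 ± 0.162 (SE) that did not pass the test (limma adjusted p = 0.171). The authors' deposited table lists Gramd1b on ezetimibe at −0.82 (adjusted p = 0.00203), and Gramd1a on the control diet at −0.82 (adjusted p = 0.00602). Every KO library was below every WT library of the same diet for Gramd1b and for Gramd1c. Which exons were deleted is not given in the sources used here, so the remaining reads may come from outside the deleted parts. Gramd1a, which encodes Aster-A (chromosome 7, 31130127 to 31155896, minus strand), did not pass the test in KO, at a log2 fold change of −0.82 ± 0.186 (SE, limma adjusted p = 0.0636) on the control diet and −0.40 ± 0.172 (SE, limma adjusted p = 0.286) on ezetimibe. Npc1l1, the gene of the target of ezetimibe (chromosome 11, 6211013 to 6230143, minus strand), had 15505 ± 2122 (SD, n = 4) in WT and 15840 ± 3436 (SD, n = 3) in KO on the control diet, a log2 fold change of 0.02 ± 0.168 (SE, limma adjusted p = 0.979). None of the 13 tested genes within 2 Mb of Gramd1b or of the 32 within 2 Mb of Gramd1c, the targeted genes left out, passed the test in KO on either diet. On the control diet 1 and 8 of them had an unadjusted p under 0.05, against 2106 of all 14299 genes tested. On ezetimibe 1 and 7 did, against 2352. Median log2 fold changes were −0.0577 near Gramd1b and −0.333 near Gramd1c on the control diet, and −0.055 and −0.223 on ezetimibe. Cd200r2, near Gramd1c, was lower in KO control than in WT ezetimibe (log2 fold change −0.92, limma adjusted p = 0.0461).

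**Figure D1:**
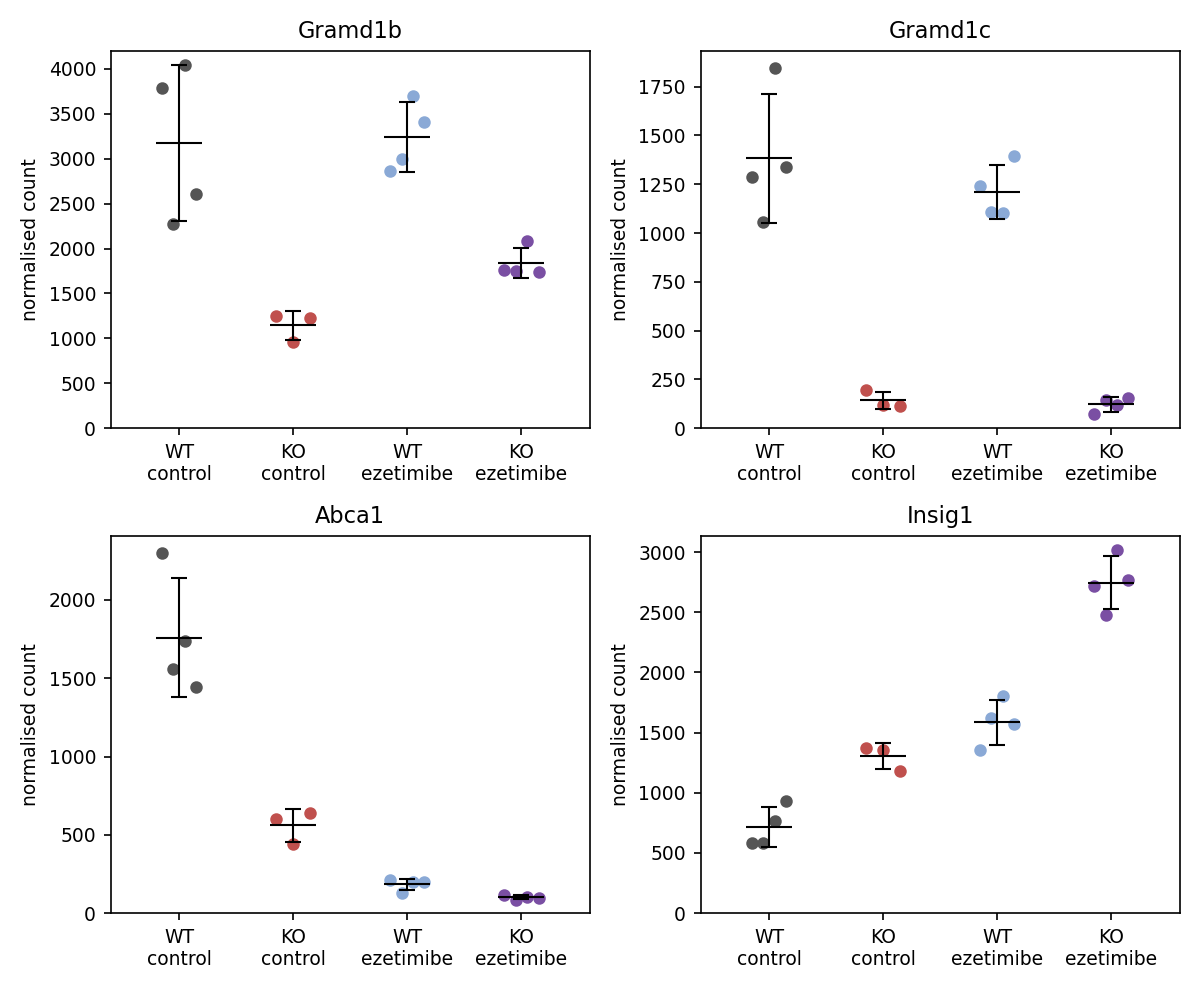
Normalised counts of Gramd1b, Gramd1c, Abca1 and Insig1 (vertical axes, from 0) in each library (points) of the 4 groups (horizontal axes), with the group mean (long bar) and SD (capped bar). Abca1 averaged 1759 in WT control, 560.5 in KO control, 183 in WT ezetimibe and 101 in KO ezetimibe, and Insig1 averaged 716, 1306, 1586 and 2746 in the same order.

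The first comparison asked what loss of both Aster proteins changed in the jejunum on the control diet. Abca1, a cholesterol efflux transporter induced by liver X receptors (LXR), fell from 1759 ± 379.5 normalised counts (SD, n = 4) in WT to 560.5 ± 107 (SD, n = 3) in KO, a log2 fold change of −1.64 ± 0.194 (SE, limma adjusted p = 0.0022). The score of the LXR target list, which holds Abca1, differed by −0.239 in KO (exact permutation p = 0.229, 0.286 adjusted), with overlap of the groups. On ezetimibe it differed by −0.0913 (exact permutation p = 0.343, 0.404 adjusted), again with overlap. Insig1, a sterol-regulated brake on SREBP processing, rose by 0.89 ± 0.149 (log2, SE, limma adjusted p = 0.0309). Among 20 cholesterol synthesis genes, 2 rose at the level of all genes tested, Tm7sf2 by 0.67 ± 0.124 and Mvk by 0.59 ± 0.12 (log2, SE, limma adjusted p = 0.047 for each). Genes of dividing cells were lower, with Mki67 at −1.50 ± 0.288, Bub1 at −1.91 ± 0.378, Aspm at −1.69 ± 0.333, Knl1 at −1.56 ± 0.281 and Anln at −1.51 ± 0.303 (log2, SE, limma adjusted p between 0.0424 and 0.047). Ddah1, an enzyme that degrades methylated arginines, rose by 1.58 ± 0.203 (log2, SE, limma adjusted p = 0.00338), from 168 ± 34.7 (SD, n = 4) to 497 ± 77.7 (SD, n = 3).

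As a list, the cholesterol synthesis genes had a median log2 fold change of 0.33 in KO on the control diet, with 19 of 20 positive and 6 higher when adjusted over the list alone (camera adjusted p = 4.59e-07). The list's mean log2 level was 9.18 ± 0.119 (SD, n = 3) in KO and 8.84 ± 0.19 (SD, n = 4) in WT. The 2 groups did not overlap, and the two-sided exact permutation test gave p = 0.0571 (0.0952 after Benjamini-Hochberg adjustment over 20 tests), where 0.0286 is the smallest the 35 assignments allow. Of 12 sterol uptake and feedback genes, Insig1 rose at the level of all genes tested, 6 were higher when adjusted over the list alone, and the median was 0.30 (camera adjusted p = 0.000615). The list's score was 9.99 ± 0.0261 (SD, n = 3) in KO against 9.66 ± 0.115 (SD, n = 4) in WT (exact permutation p = 0.0286, 0.0572 adjusted). With an estimated correlation between genes, the adjusted p was 0.256 for the synthesis list and 0.0718 for the uptake list, so neither held. Both passed with fry.

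Lists of cell type markers and of fatty acid oxidation were tested in the same comparison. The proliferation list had a median of −1.18 (2 of 14 genes called by limma, 11 lower when adjusted over the list alone, camera adjusted p = 1.54e-08), and the Paneth cell list one of −1.62 (0 of 8 called by limma, all 8 lower when adjusted over the list alone, camera adjusted p = 4.59e-07). Lyz1 and Mmp7, Paneth cell products, had log2 fold changes of −1.70 ± 0.46 and −1.67 ± 0.47 (SE) that did not pass limma across all genes. Both are listed as lower in the authors' deposited table (DESeq2 adjusted p = 0.0209 and 0.0186). So are Ang4, Defa17 and Defa22 (DESeq2 adjusted p between 0.0193 and 0.0245). The T and NK cell list had a median of −0.61 (0 of 12 called by limma, 8 lower when adjusted over the list alone, camera adjusted p = 3.6e-06), with Itgae, an integrin of intraepithelial lymphocytes, at −0.94 ± 0.24 (SE, limma adjusted p = 0.0855). Itgae, Cd7 and Ccl5 are listed as lower in the authors' deposited table (DESeq2 adjusted p = 0.00619, 0.0363 and 0.0323). Among 17 genes of fatty acid oxidation and PPARα response, 15 were positive and 1 was higher when adjusted over the list alone (median 0.31, camera adjusted p = 9.37e-06). The MHC class II list had a median of −0.90 (0 of 7 called, 6 lower when adjusted over the list alone, camera adjusted p = 0.000647), with KO control replicate 1 at a score of 9.84 and the other 2 KO control libraries at 11.3 and 11.6. Without that library the MHC class II median was −0.391 and no longer passed. With a proliferation score as a covariate the Paneth cell (median −0.114) and MHC class II (−0.735) lists no longer passed. With an estimated correlation these 5 lists had adjusted p of 0.316, 0.316, 0.316, 0.166 and 0.573, in the order given, so none held. With fry the fatty acid oxidation and PPARα list passed, and the proliferation, Paneth cell, T and NK cell and MHC class II lists did not.

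In total limma called 53 of 14299 genes on the control diet, 21 higher and 32 lower in KO, and 2106 had an unadjusted p under 0.05. The count depended on the tool, with 12 genes by edgeR, 10 by limma-voom and 442 by DESeq2, which included all 53. The share higher was 39.6%, against 23.7% of 38 called genes with TMM scaling and 20% of only 5 with quantile normalisation. It became 126, 4, 7 and 18 without WT control replicates 1 to 4 in turn and 3, 41 and 4 without KO control replicates 1 to 3, while Gramd1c, Gramd1b and Abca1 passed in each of these 7 fits and Ddah1 in 6. The other calls named here mostly ended, with Tm7sf2 past the threshold in 3 of the 7 fits, Insig1 and Mki67 in 2, Bub1, Aspm, Knl1 and Anln in 1 and Mvk in 0. The authors' deposited table for this comparison lists 424 genes, 194 higher and 230 lower in KO, with Abca1 at a log2 fold change of −1.65.

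On the ezetimibe diet the same genotypes were compared with cholesterol import through NPC1L1 blocked in both. Gramd1c was the 1 gene that limma, edgeR and limma-voom each called. The cholesterol synthesis list had a median of 0.23, with 17 of 20 genes positive, 0 called and 4 higher when adjusted over the list alone (camera adjusted p = 0.00038). Its score was 9.92 ± 0.151 in KO and 9.69 ± 0.0863 in WT (SD, n = 4 each, exact permutation p = 0.0286, 0.0572 adjusted), without overlap of the groups. Insig1 had a log2 fold change of 0.80 ± 0.14 (SE), Msmo1 one of 0.55 ± 0.10, Npc1l1 one of 0.59 ± 0.156 and Abca1 one of −0.84 ± 0.18, none past the test (limma adjusted p between 0.171 and 0.223). The enterocyte list had a median of 0.31 with all 12 genes positive (0 called, 2 higher when adjusted over the list alone, camera adjusted p = 2.93e-05), with Alpi, a brush border phosphatase, at 0.63 ± 0.17 (SE, limma adjusted p = 0.223). The proliferation list had a median of −0.68 (0 of 14 called by limma, camera adjusted p = 2.93e-05), the T and NK cell list one of −0.54 (0 of 12 called by limma, 6 lower when adjusted over the list alone, camera adjusted p = 4.83e-05) and the myeloid list one of −0.59 (0 of 10 called by limma, camera adjusted p = 0.00334), which was −0.268 without KO ezetimibe replicate 3. Cd3g, of the T and NK cell list, is listed at −0.70 in the authors' deposited table (DESeq2 adjusted p = 0.0361). With a proliferation score as a covariate the enterocyte (median 0.0917) and myeloid (−0.206) lists no longer passed. With an estimated correlation the adjusted p was 0.576 for each of these 5 lists, so none held. None of them passed with fry either. At an unadjusted p under 0.05 there were 2352 genes, and DESeq2 called 86. The authors' deposited table lists 72 genes, 47 higher and 25 lower, with Insig1 at 0.79, Abca1 at −0.86 and Npc1l1 at 0.59 (log2 fold change).

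The next comparison asked which genes differed in WT mice between the diets with and without ezetimibe. No label gives cage or day, so these were not separated from diet. Abca1 fell from 1759 ± 379.5 normalised counts (SD, n = 4) to 183 ± 37.9 (SD, n = 4), a log2 fold change of −3.26 ± 0.18 (SE, limma adjusted p = 9.51e-08), and Abcg5, part of a sterol exporter, fell by 0.83 ± 0.135 on the log2 scale (SE, limma adjusted p = 0.0137). Of 20 cholesterol synthesis genes 11 rose and none fell, and 18 were higher when adjusted over the list alone. Cyp51 rose by 1.44 ± 0.191, Fdft1 by 1.43 ± 0.169, Sqle, which encodes squalene epoxidase, by 1.37 ± 0.225, and Mvk by 1.33 ± 0.111 (log2, SE, limma adjusted p between 1.97e-05 and 0.0139). The list median was 0.84 (camera adjusted p = 1.76e-46, and adjusted p = 0.00128 with an estimated correlation). Its score rose from 8.84 ± 0.19 to 9.69 ± 0.0863 (SD, n = 4 each, exact permutation p = 0.0286, 0.0572 adjusted).

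Of 12 sterol uptake and feedback genes 3 rose, including Insig1 by 1.17 ± 0.14 and Srebf2, the regulator of sterol synthesis genes, by 0.80 ± 0.11 (log2, SE). The list median was 0.24 (camera adjusted p = 1.97e-06, and adjusted p = 0.00433 with an estimated correlation). The LXR target list had a median of −0.12 and a mean of −0.54 (2 of 10 genes lower, Abca1 and Abcg5, camera adjusted p = 2.63e-06), and its adjusted p was 0.226 with an estimated correlation. Its median was −0.0456 without WT control replicate 1, −0.214 without WT control replicate 3 and −0.192 without WT ezetimibe replicate 3. Among 15 fatty acid synthesis genes none was called, and the median was 0.15 (camera adjusted p = 0.179).

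The interferon response list was tested on the same libraries. It had a median of 1.22, with Isg15 alone called of 14 genes at 1.396 ± 0.255 (log2, SE, limma adjusted p = 0.0275) and 12 higher when adjusted over the list alone (camera adjusted p = 3.64e-19). With an estimated correlation the adjusted p was 0.101. The T and NK cell list had a median of 0.44 (0 of 12 called, camera adjusted p = 5.13e-07) and the Paneth cell list one of −1.08 (0 of 8 called, 7 lower when adjusted over the list alone, camera adjusted p = 1.06e-07), with an adjusted p of 0.269 for each with an estimated correlation. Paneth cell scores in WT control were 12.0 and 12.2 in replicates 2 and 4 but 10.4 and 10.8 in replicates 1 and 3. WT ezetimibe scores, from 9.36 to 11.38, overlapped them. The Paneth cell median of −1.62 in KO on the control diet uses the same WT control libraries. H2-Q10, a class I gene of the major histocompatibility complex, rose from 63.9 ± 18.0 to 337 ± 38.6 (SD, n = 4 each), by 2.42 ± 0.283 (log2, SE, limma adjusted p = 0.000788). It belongs to a family of near-identical copies, and reads may be shared between them.

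**Figure D2:**
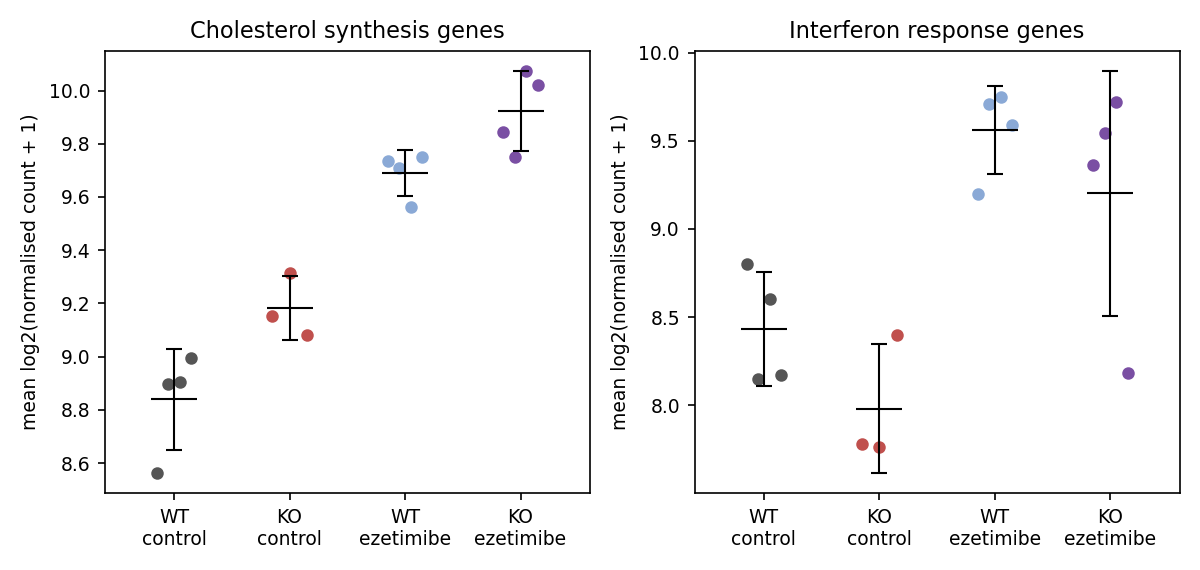
Mean log2(normalised count + 1) of the cholesterol synthesis list (left) and the interferon response list (right) in each library (points) of the 4 groups, with group mean (long bar) and SD (capped bar). The vertical axes do not start at 0. KO ezetimibe replicate 4 lay at 8.18 for interferon genes, where the other 3 libraries of its group lay between 9.36 and 9.72.

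In total limma called 31 genes in WT, 29 higher and 2 lower with ezetimibe, and 726 had an unadjusted p under 0.05. DESeq2 called 94, edgeR 34 and limma-voom 26, and the count became 20, 17 and 18 without WT control replicate 3, WT ezetimibe replicate 2 or WT ezetimibe replicate 4. Abca1, H2-Q10, Cyp51, Fdft1, Mvk, Insig1 and Srebf2 passed in each of 8 fits without 1 library, Sqle in 6, Abcg5 in 5 and Isg15 in 2.

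The response to ezetimibe was measured again in KO mice. Abca1 fell from 560.5 ± 107 (SD, n = 3) to 101 ± 12.6 (SD, n = 4), a log2 fold change of −2.46 ± 0.194 (SE, limma adjusted p = 1.86e-05). Of 20 cholesterol synthesis genes 9 rose, including Msmo1 by 1.12 ± 0.11, Nsdhl by 0.96 ± 0.13, Sqle by 1.29 ± 0.243 and Cyp51 by 1.24 ± 0.206 (log2, SE, limma adjusted p between 0.000236 and 0.0355), and 18 were higher when adjusted over the list alone. The list median was 0.69 (camera adjusted p = 2e-15), and the adjusted p was 0.071 with an estimated correlation. Its score rose from 9.18 ± 0.119 (SD, n = 3) to 9.92 ± 0.151 (SD, n = 4, exact permutation p = 0.0286, 0.0572 adjusted). Of 12 sterol uptake and feedback genes 4 rose, including Insig1 by 1.07 ± 0.15, Srebf2 by 0.62 ± 0.12 and Npc1l1 by 0.86 ± 0.168 (log2, SE), with Npc1l1 at 28580 ± 4567 (SD, n = 4) on ezetimibe. The list median was 0.16 (camera adjusted p = 0.0314, and adjusted p = 0.24 with an estimated correlation), and the list no longer passed without KO control replicate 3 (median 0.259), KO ezetimibe replicate 1 (0.102) or KO ezetimibe replicate 4 (0.204), or with a proliferation score as a covariate (0.181).

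Genes of fatty acid oxidation and PPARα response were lower with ezetimibe in KO, with 3 of 17 called and 12 lower when adjusted over the list alone (median −0.48, camera adjusted p = 2.13e-08, adjusted p = 0.071 with an estimated correlation). The 3 were Acot1 at −2.10 ± 0.344, Acot2 at −1.12 ± 0.20 and Hadhb, a subunit of the mitochondrial trifunctional protein, at −0.36 ± 0.08 (log2, SE). Acot1 and Acot2 are close paralogs whose reads may be shared. The myeloid list had a median of −1.28 (1 of 10 called, C1qc at −1.77 ± 0.376, 8 lower when adjusted over the list alone, camera adjusted p = 1.9e-05), and Apoe fell by 1.86 ± 0.41 and Pla2g7 by 2.38 ± 0.466 on the log2 scale (SE). The interferon list had a median of 1.18 (0 of 14 called, all 14 higher when adjusted over the list alone, camera adjusted p = 2.13e-08), and outside it Igtp, an interferon-induced GTPase, rose by 2.22 ± 0.446 (log2, SE, limma adjusted p = 0.0431). The T and NK cell list had a median of 0.50 (0 of 12 called, 3 higher when adjusted over the list alone, camera adjusted p = 0.000662). The MHC class II list had a median of 1.13 (0 of 7 called, 6 higher when adjusted over the list alone, camera adjusted p = 0.000195), which was 0.618 without KO control replicate 1. With an estimated correlation the adjusted p was 0.26 for the myeloid, 0.423 for the interferon, 0.714 for the T and NK cell and 0.678 for the MHC class II list.

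In total limma called 104 genes in KO, 62 higher and 42 lower with ezetimibe (59.6% higher, against 47.8% with TMM scaling), and 3278 had an unadjusted p under 0.05. By other tools the count was 1155 (DESeq2), 97 (edgeR) and 41 (limma-voom), and it became 5, 9 and 442 without KO control replicates 1 to 3 in turn and 255, 16, 8 and 456 without KO ezetimibe replicates 1 to 4. Abca1, H2-Q10, Insig1 and Msmo1 passed in each of these 7 fits, Nsdhl in 6 and Cyp51 in 4. Sqle, Npc1l1, Srebf2, Igtp, Pla2g7 and Hadhb passed in 3 of the 7, C1qc in 2 and Apoe in 1.

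**Figure D3:**
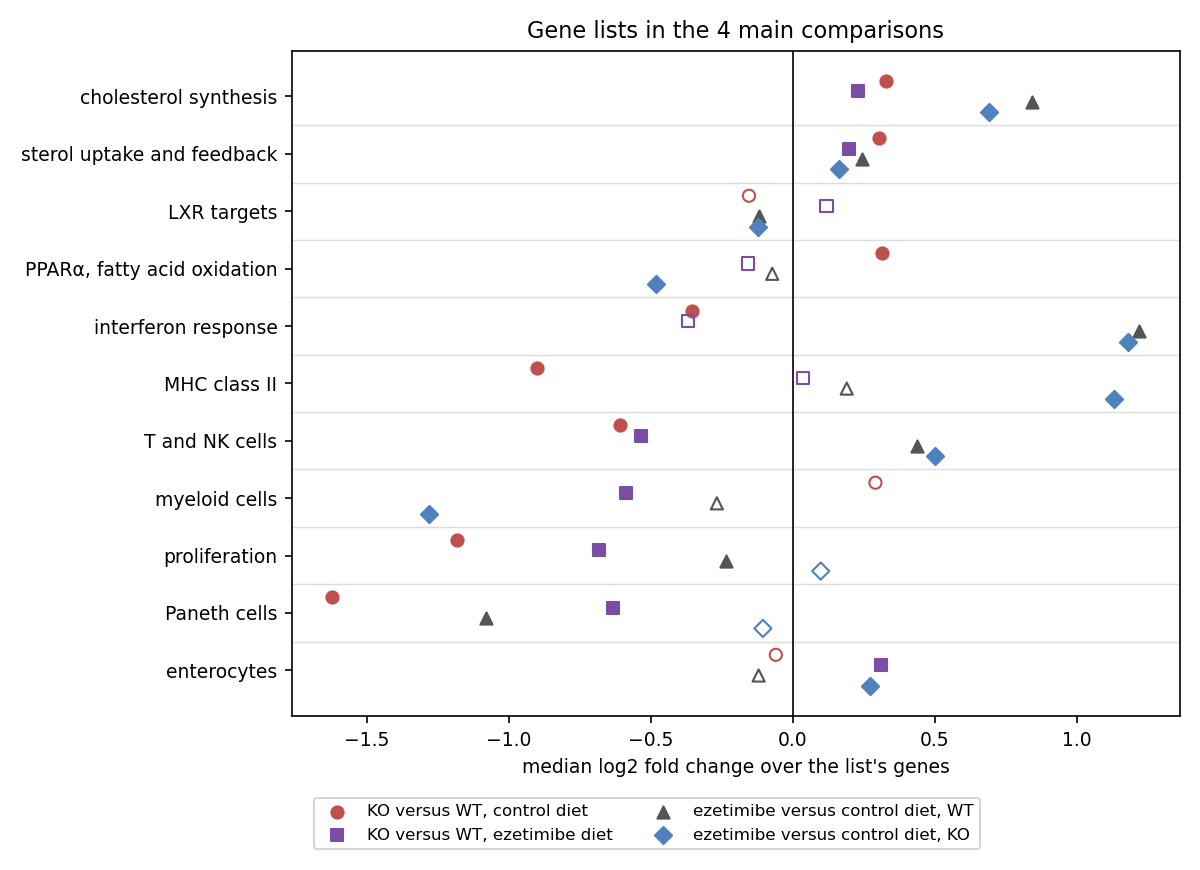
Median log2 fold change (horizontal axis) of 11 gene lists (rows) in 4 comparisons (symbols), filled where the camera test with a preset correlation gave an adjusted p under 0.05. The cholesterol synthesis medians lay at 0.33, 0.23, 0.84 and 0.69, in the order of the legend's comparisons.

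Whether the response to ezetimibe differed between the genotypes was tested as an interaction, the response in KO minus that in WT. No gene passed with limma, edgeR or limma-voom (smallest limma adjusted p = 0.681), 1004 had an unadjusted p under 0.05, and DESeq2 called 5, namely Bco1, Ccne2, Fosb, Kansl1 and Naip6. Fosb, an immediate-early transcription factor, had an interaction of 2.52 ± 0.496 (log2, SE). Bco1, which cleaves carotenoids, had an interaction of 2.82 ± 0.581 and Naip6, whose reads may be shared with other Naip copies, one of 1.10 ± 0.218 (log2, SE). For the cholesterol synthesis list the median interaction was −0.15 (camera adjusted p = 0.324) and 0 of 20 genes were called. The 5 lists that passed the preset camera test were fatty acid oxidation and PPARα (median −0.43), myeloid (−0.92), enterocyte (0.40), MHC class II (0.98) and Paneth cells (0.93), and none held with an estimated correlation (adjusted p between 0.26 and 0.976). These results share the KO control libraries with the KO effect on the control diet and with ezetimibe in KO. The MHC class II list no longer passed without KO control replicate 1 (median 0.469). The Paneth cell list no longer passed without WT control replicates 2 (0.727) or 4 (0.658), WT ezetimibe replicate 3 (0.625) or KO control replicate 3 (0.806).

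The last comparison set loss of the Aster proteins beside drug blockade, KO on the control diet against WT on ezetimibe. Abca1 was higher in KO control by 1.61 ± 0.194 (log2, SE, limma adjusted p = 0.00105), and 8 of 20 cholesterol synthesis genes were lower and none higher (list median −0.53, camera adjusted p = 1.68e-09, adjusted p = 0.162 with an estimated correlation), including Cyp51 at −1.002 and Mvk at −0.74. The proliferation list was lower too (2 of 14 called, 7 lower when adjusted over the list alone, median −0.89, camera adjusted p = 3.72e-05, adjusted p = 0.482 with an estimated correlation). With a proliferation score as a covariate the cholesterol synthesis list passed (median −0.422), as did 4 of its 8 called genes, Mvk, Nsdhl, Msmo1 and Dhcr7, while Cyp51, Pmvk, Idi1 and Fdft1 did not. Interferon response genes were lower, with 10 of 14 called (median −1.60, camera adjusted p = 5.07e-13, adjusted p = 0.198 with an estimated correlation), among them Ifi44 at −3.28 ± 0.659 (log2, SE). T and NK cell genes were lower with 9 of 12 called (median −0.97, camera adjusted p = 1.08e-11, adjusted p = 0.162 with an estimated correlation). Limma called 449 genes, 126 higher and 323 lower, DESeq2 called 757, edgeR 420 and limma-voom 406, and the count was 269, 177, 196 and 285 without WT ezetimibe replicates 1 to 4 in turn and 68, 247 and 325 without KO control replicates 1 to 3.

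The genes called for KO on the control diet and for ezetimibe in WT shared 3 that rose, Insig1, Mvk and Tm7sf2, and 1 that fell, Abca1. Both comparisons use the 4 WT control libraries, and no expected number under shared controls was computed for these counts. Across 14297 genes their fold changes correlated with r = 0.224. Simulated groups with no effect and a shared control group, all drawn from the deviations of the 15 libraries, gave a mean of 0.46. Their central 95% range was 0.00203 to 0.766, and the observed covariance of 0.027 lay below the simulated mean of 0.0473. With the controls split into 2 and 2, r lay between −0.227 and 0.0111 over 6 splits (mean −0.115). Genes are not independent replicates. The response to ezetimibe correlated between the genotypes with r = 0.40, inside the central 95% range of −0.463 to 0.491 simulated without effects. In both genotypes 17 genes rose, against 0.126 for independent lists. The 17 included 8 cholesterol synthesis genes, Cyp51, Fdft1, Idi1, Msmo1, Mvk, Nsdhl, Pmvk and Sqle.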

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

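The tests of the T and NK cell pattern and the scaling test of the cholesterol synthesis pattern were chosen after the result was seen, and the covariate and left-out tests of the other patterns after the group comparisons were seen but before their own values. A clock covariate for the cholesterol synthesis list (median 0.308) and a reading of a single library as excluding the drug were also tried, and neither is weighed here. Each of 49 measures was checked in every group of 4 libraries, 147 sets in all, though the measures are not independent. In 7 sets (4.76%) a library lay far from the other 3 by Dixon's ratio, about the 5% that chance gives. KO control, with 3 libraries, was not checked. KO ezetimibe replicate 3 was high for Gramd1b at 2090 normalised counts (others 1740 to 1760), for Gramd1a at 243 (others 184 to 185) and for the distal intestine list at a score of 11.3 (others 10.3 to 10.4). WT ezetimibe replicate 3 was high for the xenobiotic metabolism list at 11.3 (others 10.2) and for Abcg5 at 3450 (others 2650 to 2780). KO ezetimibe replicate 4 was high for the tuft cell list at 7.14 (others 6.61 to 6.69), and WT ezetimibe replicate 4 was low for the T and NK cell list at 8.01 (others 8.37 to 8.44).

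The response to ezetimibe differed between the genotypes, by the preset camera test of the interaction, for the fatty acid oxidation and PPARα list (median −0.433), the MHC class II list (0.977), the enterocyte list (0.404), the Paneth cell list (0.928) and the myeloid list (−0.922). None of the 5 held with an estimated correlation. The interaction, the KO effect on the control diet and ezetimibe in KO all use the same KO control libraries, so their list results are not independent. MHC class II scores were 9.84 to 11.64 in KO control, 11.67 to 11.98 in WT control, 11.70 to 12.20 in WT ezetimibe and 11.34 to 12.52 in KO ezetimibe. Without KO control replicate 1 the MHC class II median was 0.469 and no longer passed, and the Paneth cell list no longer passed without WT control replicates 2 or 4, WT ezetimibe replicate 3 or KO control replicate 3 (medians 0.727, 0.658, 0.625 and 0.806). With a proliferation score as a covariate neither of these 2 lists passed (0.927 and 0.381).

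Cholesterol synthesis genes were higher in KO on the control diet by the preset camera test (median 0.328), with 2 of 20 genes called and an adjusted p = 0.256 with an estimated correlation. Fewer dividing crypt cells in the KO samples would have to take up the difference, but with the proliferation score as a covariate the median was 0.491. With a score of position along the intestine as a covariate it was 0.393. The bound was 0.164 and both values exceed it, which argues against fewer dividing cells or position as the whole cause. Relative to all genes the median was 0.334, and 0.284 under quantile scaling, the lower of 2 scalings, above the bound of 0.167. One factor per library moves all genes alike and cancels in that measure, as under TMM (0.334). The measure therefore decides nothing about the size factors. A response to loss of the Aster proteins stays a hypothesis, found and tested on the same data, and the unadjusted camera p with an estimated correlation was 0.0697 with the proliferation covariate and 0.0321 with the position covariate.

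T and NK cell markers were lower in KO by the preset camera test, at −0.571 as the mean of the medians on the 2 diets, with 0 of 12 genes called by limma on either diet and adjusted p of 0.316 and 0.576 with an estimated correlation. For a smaller share of lamina propria in the KO samples, the median of 5 other non-epithelial lists had to reach the bound of −0.286. It was −0.144, short of the bound but within 1 standard error (0.225) of it, so this was not decided. That standard error is the spread over the 5 lists and not between mice. Dilution by enterocyte RNA needs all such lists to fall alike, and their median lay 1.9 standard errors from that of the T and NK cell list, with B and plasma cells at −0.955 and fibroblasts at 0.422, while adipocyte markers, outside these 5 lists, had medians of 1.70 and 1.90 on the 2 diets without passing the test. On the control diet goblet cell scores were 12.87 to 12.96 in KO and 12.86 to 13.10 in WT. Enteroendocrine scores were 7.70 to 8.06 and 7.84 to 7.97, and tuft cell scores 6.16 to 6.45 and 5.93 to 6.73. T and NK cell scores, at 7.04 to 7.58 in KO, lay below the 7.59 to 8.20 of WT. Goblet and enteroendocrine values argue against dilution that lowers all other lists alike on that diet, though Paneth cell and proliferation lists fell. A smaller share of lamina propria and fewer lymphocytes in KO cannot be told apart, because the 5 lists scatter too widely.

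Interferon response genes were higher with ezetimibe by the preset camera test, at 1.2 as the mean of the medians in the 2 genotypes, with 1 of 14 genes called in WT and 0 in KO and adjusted p of 0.101 and 0.423 with an estimated correlation. With the T and NK cell score as a covariate this was 0.848, above the bound of 0.6, and the lowest medians without any 1 library were 0.989 in WT and 0.931 in KO (1.08 as the mean of both genotypes), which argues against more lymphocytes or 1 high library as the whole cause, though with that covariate the camera p was 0.127 with an estimated correlation in the genotype where it was higher. KO ezetimibe replicate 4 had an interferon score of 8.18, inside the range of the control diet, with a cholesterol synthesis score of 10.0, above it. A cage or day that differs between the diets could also be a source, and with 0 of 15 libraries labelled by cage or day it cannot be told apart from the drug.

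For KO against WT on the control diet, 1 of the 35 splits of the 7 libraries, the real one, called as many as 53 genes. The highest other split called 4. This is the smallest share that 35 splits allow, in 1 of 6 comparisons. Splits that mix the genotypes also put real differences into the shared spread, which lowers their counts. The real count thus stood out among the splits, but chance was not excluded. The same held for KO control against WT ezetimibe, with 449 genes in the real split, at most 1 in the others and 1 of 35 as large. For KO against WT on ezetimibe 2 of 35 splits called 1 gene, the highest other also 1, so chance cannot be excluded for the count, which says nothing against Gramd1c, a gene named in advance. For ezetimibe in WT 2 of 35 splits called at least 31 genes, the highest other 62, so chance cannot be excluded for the count. That other split had control replicates 1 and 2 and ezetimibe replicates 1 and 3 on one side, which points to a structure of the samples. These 4 libraries had the highest Dbp levels of the 8, from 415 to 911.3 normalised counts against 41.3 to 120 in the others. For ezetimibe in KO 2 of 35 splits called at least 104 genes, so chance cannot be excluded for that count either. The highest other split called 139, with the 3 control libraries and ezetimibe replicate 4 on one side. For the interaction the real count was 0, which all 100 splits drawn reach by construction (highest other 2), so nothing was tested there.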

How the results depend on the processing

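Alternatives with a proliferation or clock covariate, DESeq2 without a filter, or without the 2 libraries at the ends of the first principal component were chosen after seeing the data. Of 1655 values of 64 list results under an alternative, 1399 kept direction and side of the threshold, 245 lost the call and 11 reversed. Of 3154 values of 135 single-gene results, 2520 kept both, 595 lost the call, 18 gained one and 21 reversed. The cause of these changes was not tested. Less power with fewer libraries is not enough, since leaving out WT control replicate 1 raised the KO count on the control diet from 53 to 126. Depth limits low genes most, and the filter kept genes with at least 10 normalised counts in at least 3 libraries, so lower values remain in some libraries. Counts of called genes moved by over 1.5 times as follows. For KO on the control diet (53) they were 17 with a pseudocount of 5, 12 without a filter, 5 with quantile normalisation, 3 with the 2 groups alone, 12 with edgeR, 442 with DESeq2, 424 with DESeq2 unfiltered, 10 with limma-voom, 149 with the proliferation covariate and 25 without the 2 end libraries, and 3 to 126 with each library left out. For KO on ezetimibe (1) they were 2 with quantile normalisation, 3 with the 2 groups alone, 86 and 72 with DESeq2 filtered and unfiltered, 3 with the proliferation and 2 with the clock covariate. For ezetimibe in WT (31) they were 94 and 93 with DESeq2, and 17 to 34 with each library left out. For ezetimibe in KO (104) they were 54 without a filter, 330 with the stricter filter, 16 with the 2 groups alone, 1155 and 1110 with DESeq2, 41 with limma-voom, 2087 with the proliferation and 54 with the clock covariate, 12 without the 2 end libraries, and 5 to 456 with each library left out. For the interaction (0) they were 5 and 3 with DESeq2 and 0 to 1 with each library left out. For KO control against WT ezetimibe (449) they were 298 with quantile normalisation, 757 and 752 with DESeq2, 1081 with the proliferation covariate, and 68 to 325 with each library left out. The cholesterol synthesis list, with medians of 0.328, 0.231 and 0.69 for KO on the control diet, KO on ezetimibe and ezetimibe in KO, lost its call with an estimated correlation, and for KO on ezetimibe with fry also, while ezetimibe in WT kept it throughout.

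With the proliferation score as a covariate these list medians reversed: for KO on the control diet lipid absorption (−0.0852), stem cells (0.529) and proliferation itself (0.019), for KO on ezetimibe Paneth (0.399), proliferation (0.0523) and B and plasma cells (0.308), for ezetimibe in WT proliferation (0.05), and for KO control against WT ezetimibe lipid absorption (−0.0165) and stem cells (0.58). That score is the mean of the proliferation list itself, so the list's own adjusted medians lie near 0 by construction. Their signs carry no information, though they are counted among the reversed list values. The mitochondrial list for KO on ezetimibe reversed to −0.0303 with quantile normalisation, and the sterol transport list for KO control against WT ezetimibe to 0.0217 with the stricter filter. Genes without a call also changed sign. Npc1l1 in KO on the control diet was −0.0216 with quantile normalisation, −0.0355 with the replicate block, −0.414 with the proliferation covariate, −0.0393 without the 2 end libraries and −0.142 to 0.17 with each library left out. Gramd1b for ezetimibe in WT was −0.066 with the proliferation covariate, −0.0186 without the 2 end libraries and −0.0845 to 0.192 with each library left out. Gramd1c for ezetimibe in KO was −0.366 to 0.0095 with each library left out, and its interaction was 0.00261 with quantile normalisation, 0.0597 and 0.0445 with the proliferation and clock covariates and −0.212 to 0.178 with each library left out. The correlation of the KO and ezetimibe effects, 0.224, reversed to a mean of −0.115 with the controls split.

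Replicate numbers were not used as pairs, since only 12 of 21 same-numbered pairs of different groups had a correlation of deviations over 0.1 (range −0.242 to 0.331), where pairing needed all of them. Partial sharing stays open, with a mean of 0.110 against −0.0368 for differently numbered pairs and 8 of 15 libraries correlating best with their own number. With the replicate number as a block, calls were 231 for KO on the control diet, 6 for KO on ezetimibe, 54 for ezetimibe in WT, 1915 for ezetimibe in KO, 0 for the interaction and 680 for KO control against WT ezetimibe, and the sterol uptake and feedback list for ezetimibe in KO lost its call (median 0.207, adjusted p = 0.103).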

Other observations

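The correlation of clock genes and the clock covariate were chosen after the result was seen. Clock genes varied widely between libraries of the same group. In WT control, Dbp had 867, 763.8, 49.5 and 120 normalised counts in replicates 1 to 4, and Per3, a clock repressor, had 402, 469.5, 55.6 and 68.3. Arntl, the activator usually expressed in antiphase to Dbp, had 183, 109.9, 476 and 297.5 in the same libraries. In WT ezetimibe, Dbp had 911.3, 41.3, 415 and 91.0 and Arntl had 155, 555, 242 and 512. The KO libraries covered a narrower range of Dbp, from 69.0 to 398. The clock list passed the camera test in none of the 4 main comparisons (adjusted p between 0.219 and 0.687), and this spread within groups leaves a difference between groups unmeasured. The list holds both Arntl and Dbp, so a change of phase between groups could cancel in this test of 1 direction.

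A candidate explanation is that mice of the same group were killed at different times of day. Clock genes that had not been looked at when this was proposed, Nr1d1, Nr1d2, Per2 and Ciart less Clock, rose with Dbp and Per3 across the 15 libraries (Spearman rho = 0.818, permutation p = 0.00038, and Pearson r = 0.822, permutation p = 0.00017). Without the 2 libraries farthest from the median, r was 0.802. This was the only such relation computed on those genes, after one of Dbp and Per3 with Arntl and Npas2, whose values had been seen, was dropped. All of these genes belong to the same clock, so the relation shows that they moved together and cannot tell the cause. No label gives a time of collection, so a different time of day and a shift of the clock itself within groups both stay open. With a clock score as a covariate limma called 78 genes for KO on the control diet, 30 for ezetimibe in WT and 54 for ezetimibe in KO.

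Adipocyte markers had the highest median in KO of any list, 1.70 on the control diet and 1.90 on ezetimibe, without passing the test (camera adjusted p = 0.146 and 0.0872). Fabp4 lay between 30.8 and 261.5 normalised counts in the KO control libraries, and at 5.73, 163, 4.12 and 9.17 in those of WT control. The B and plasma cell list had a median of −1.30 in KO on ezetimibe (0 of 11 called, camera adjusted p = 0.0314, adjusted p = 0.646 with an estimated correlation), and no longer passed without WT ezetimibe replicates 2 or 4 or KO ezetimibe replicates 3 or 4 (medians −1.08, −1.15, −1.14 and −1.01). That call also ended with the stricter filter, TMM scaling, edgeR, DESeq2 and fry, and the median turned to 0.308 with the proliferation covariate. Fabp6, an ileal bile acid-binding protein, had 2535 normalised counts in KO ezetimibe replicate 3 and between 107 and 321 in the other 3 libraries of that group.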
